A study of Oryza sativa with 12 samples.

How the data were processed

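Gene expression was measured in developing rice seeds on an Affymetrix rice array, with 12 arrays in 4 groups of 3: the wild-type variety Wuxiangjiang9 (WT), whose seed lysine is labelled normal, and the lines GR14, 35S-15 and HFL1, whose seed lysine is labelled high. The sample labels give 10 days after flowering and the series' design text gives 15, and the values cannot settle which is right. Plants were grown in a field, RNA was extracted with Trizol and checked on a Bioanalyzer, and biotinylated cRNA was made from 6 ug of total RNA, per the labels' protocols. The sample titles give no replicate number within a group, so replicates were numbered in accession order, which pairs nothing. The labels do not say whether the 3 arrays of a group came from separate plants, so every p-value here measures only the spread between these arrays, which may be technical.

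The deposited values are MAS5 signal intensity per probe set on a linear scale, as the submitters' processing notes name that tool. Its version and settings are not given in the sources used here. All values were above 0. The mean without the lowest and highest 2% was about 500.1 in every column, so the authors had scaled each array. No detection calls were among the values used here. Depth has no meaning for arrays; the number of arrays limits the precision. The number of per-sample columns left unused was 0.

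From the deposited intensity, log2(signal) was taken with no further normalization between arrays. The 123 AFFX and 64 RPTR probe sets were left out of the tests, the latter serving as a check of the labels. Of 57381 probe sets, 31792 were tested, namely those above their array's median in at least 3 of the 12 arrays. A 4-group model was fitted with limma 3.58.1 (lmFit, then eBayes with an intensity trend) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment at 0.05. The contrasts were each line against WT, the mean of the 3 lines against WT, each pair of lines, and the departure of HFL1 from the sum of the GR14 and 35S-15 differences. That HFL1 combines the other 2 is known from earlier work on these lines; the labels do not state it. Errors of log2 folds are standard errors (SE) of the fit, and errors of log2 levels are SDs over 3 arrays.

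Probe sets were named from an array annotation table, updated through gene identifiers with the RefSeq gene table of assembly ASM3414082v1. By that annotation 22436 probe sets had 1 gene, 95 had several and 34850 had none. Only 2427 of the 17905 genes had an informative symbol or synonym; the others carry a LOC identifier. The tables hold no gene descriptions, so the 21 gene lists first written as description searches could not be applied as written. They were rebuilt from symbols after the annotation was seen and before the values of any gene were examined. Lists of lysine breakdown, amino acid transport and seed coat genes were dropped and a sugar transport list was added. The enzymes LKR/SDH, dihydrodipicolinate synthase and TDC1 and TDC3 were not analysed here, since no symbol identified them. No coordinates are given because the array files name no genome build. Gene lists were tested with camera at a preset correlation of 0.01, with 1 probe set per gene (the highest mean), adjusted over the lists, and beside it with an estimated correlation and with fry.

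Genes were named by a rule fixed before the data were examined. For each line against WT it took the 8 largest rises and 8 largest falls with adjusted p under 0.05, at least 2-fold change, no overlap between the 2 groups of 3 arrays, and a symbol. For the other contrasts it took 4 and 4, and from each gene list the 4 genes with the lowest p in any comparison with WT. The rule asked for a gene description, which was read here as an informative symbol. Always named were tryptophan decarboxylase, tryptamine 5-hydroxylase and lysine synthesis genes with a symbol, and the reporter probe sets. Genes given by LOC identifier, unnamed probe sets and the clock genes beyond this rule were chosen after values were seen.

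The alternatives were quantile normalization, median centring, no filter or a filter at the 70th percentile, log2(signal + 50), removal of probe sets ending in _x_at or _s_at, no intensity trend, array weights, fits of the compared groups alone, 1 probe set per gene, a 2-fold threshold, an estimated correlation, other probe sets of a gene, and leaving out each array. WT array 1 as the only control, also with an estimated correlation, was added after the data were seen. The fit was tested on simulated data for GR14 against WT with all 31792 probe sets. It called 42 of 100 probe sets changed by 1 on the log2 scale and 71 of 100 changed by 2, with 4 false calls. For HFL1 against WT over 16151 genes, camera found the simulated list shifted by 0.5 and no other list. This simulation does not show that camera passes few unchanged lists on the real arrays. There the photosynthesis list had an estimated correlation of 0.34. Other splits of the HFL1 and WT arrays passed a median of 5 lists and at most 11.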

Results

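Transcript levels were compared in developing rice seeds of a wild type with normal lysine and of 3 high-lysine lines, GR14, 35S-15 and HFL1, with 3 arrays each. The question named by the labels is how seed development relates to lysine metabolism. Spearman correlations between arrays over the 31792 tested probe sets ran from 0.925 to 0.971, and no arrays held identical values. The first principal component, with 21.7% of the variance, separated the 3 GR14 arrays from the other 9.

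The arrays are first described with 3 transcripts chosen after the values were seen because they follow the labels, so they are no check of the labels. LOC4331398 was at a log2 signal of 5.92 ± 1.19 (SD, n = 3) in the arrays labelled WT and rose in every line, by 7.76 ± 0.39 (SE) on the log2 scale in GR14, 7.64 in 35S-15 and 7.62 in HFL1. LOC4340325 rose by 8.04 ± 0.43 in GR14 and by 8.00 in HFL1, while its 35S-15 difference of 2.73 had a limma adjusted p of 0.0502. LOC9268308 rose by 5.10 ± 0.39 in 35S-15 and by 5.53 in HFL1 and had a log2 fold of -0.20 in GR14. The size of these folds is uncertain where a group lies near or below its array median, as WT does here (mean of the array medians 5.85), since no detection calls were used. HFL1 had high levels of both the transcript that was high in GR14 and the one that was high in 35S-15. Among 64 probe sets for reporter genes, RPTR-Os-K01193-1_at had log2 signals of 13.51 and 13.79 in WT arrays 2 and 3, against 4.53 in WT array 1 and at most 4.67 in the 9 arrays of the lines. OsBiP4, an endoplasmic reticulum chaperone of the BiP family, followed the same pattern, with 12.71 and 13.17 in WT arrays 2 and 3, 4.88 in WT array 1 and at most 6.13 in the lines. Comparisons with WT therefore rest on arrays labelled WT that were not alike, and each count of probe sets against WT is also given with WT array 1 alone.

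**Figure D1:**
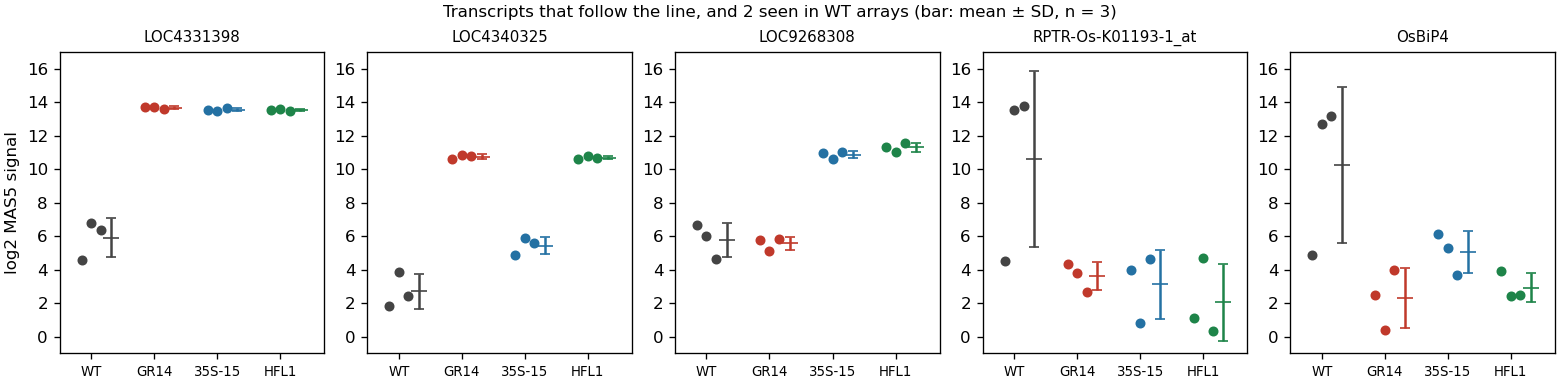
Log2 MAS5 signal per array (y axis) for 3 transcripts that follow the lines, a reporter probe set and OsBiP4, by group (x axis); points are arrays and bars are the mean ± SD of 3 arrays. LOC4331398 is high in all 9 arrays of the lines, and the reporter probe set is at 13.51 and 13.79 in WT arrays 2 and 3 only.

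In GR14, genes of the circadian clock and of photosynthesis differed from WT. Of 7 clock genes, chosen after CCA1 and GI had been seen and tested as no list, 4 passed. CCA1, a morning-phased clock transcription factor, fell by 4.35 ± 0.20 on the log2 scale, from 13.17 ± 0.10 (SD, n = 3) to 8.82 ± 0.24, with a limma adjusted p of 3.05e-07. The evening-phased clock genes moved the other way. GI rose by 1.43 ± 0.12, PRR1 by 0.85 ± 0.21 and PCL1 by 4.76 ± 1.03 (limma adjusted p 1.25e-05, 0.0349 and 0.0155); the size for PCL1 is uncertain, as its WT mean of 5.88 lies near the array median. PRR73, PRR37 and PRR95, which act between those phases, had log2 folds of 0.15, 0.41 and -0.20 and did not pass the test. In all, 1799 probe sets differed, 858 higher and 941 lower, and 1084 of them at least 2-fold. With WT array 1 alone 747 differed, and of the clock genes only CCA1 and GI passed (PRR1 0.92, adjusted p 0.197; PCL1 4.77, adjusted p 0.169). GR14 array 3 had the highest 3' minus 5' difference of the 12 arrays for 3 of 5 control transcripts (actin 5.65, GAPDH 4.20 and ubiquitin 0.14 on the log2 scale) and the lowest for EF1a (-2.29). Without it 1427 probe sets differed. PRR1 and PCL1 then had log2 folds of 0.88 and 4.64, with limma adjusted p values of 0.0678 and 0.0511.

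**Figure D2:**
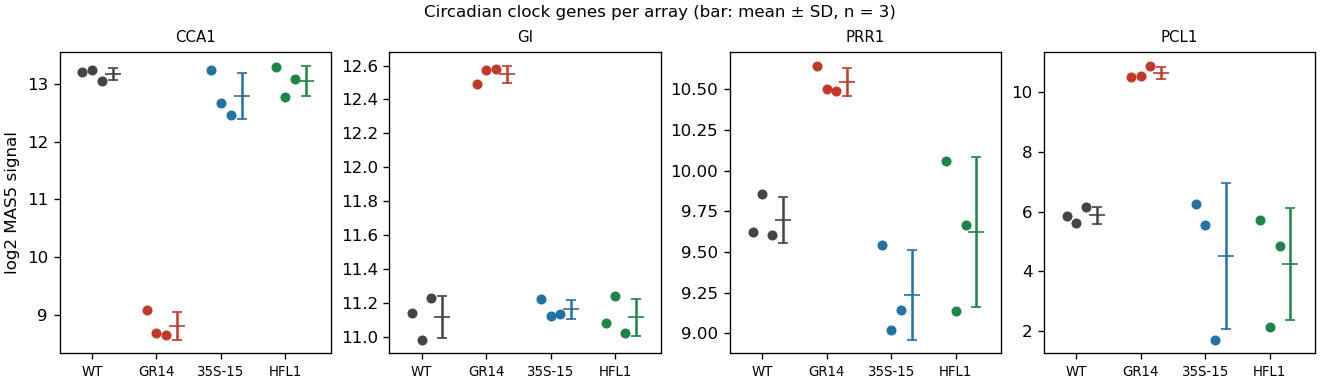
Log2 MAS5 signal per array (y axis) for 4 clock genes by group (x axis); points are arrays and bars are the mean ± SD of 3 arrays. CCA1 lies at 8.82 on average in GR14 and at 13.17 in WT, and GI, PRR1 and PCL1 are higher in GR14 than in WT.

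Of the 14 tested photosynthesis genes, which serve here as markers of the green pericarp, 5 fell and 1 rose in GR14, and 9 passed when adjusted over the list alone. The RuBisCO activase RCAA1 fell by 2.61 ± 0.17, the chlorophyll a/b-binding protein gene RCABP89 by 1.96 ± 0.17, the protochlorophyllide reductase PORA by 2.63 ± 0.31 and the photosystem I subunit PSAG by 1.91 ± 0.24 (another PSAG probe set had a log2 fold of -1.80, adjusted p 0.341). The list had a median log2 fold of -0.38 and a camera adjusted p of 0.000351, and an adjusted p of 0.399 with an estimated correlation. The embryo and aleurone list did not pass (adjusted p 0.41), although VP1, an embryo maturation regulator, rose by 1.25 ± 0.26 (0.64 with WT array 1 alone, not past the test).

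Among the 26 tested endoplasmic reticulum chaperone and unfolded protein response genes, 9 fell in GR14 and none rose, and 10 passed when adjusted over the list alone. The co-chaperone ERDJ3A fell by 2.51 ± 0.33, ERDJ3B by 1.73 ± 0.29, DER1, of endoplasmic reticulum-associated degradation, by 2.07 ± 0.42 and the disulfide isomerase-like PDIL2-3 by 1.87 ± 0.39. The camera adjusted p was 0.00032, and the adjusted p was 0.266 with an estimated correlation. OsBiP4 fell by 7.96 ± 1.74, a value set by WT arrays 2 and 3. With WT array 1 alone as control ERDJ3A had a log2 fold of -1.83, still past the test, while that of OsBiP4 was -2.59 and the folds of ERDJ3B, DER1 and PDIL2-3 were -1.05, -0.84 and -0.78, none past the test. The list had an adjusted p of 0.0474 with that control, and an adjusted p of 0.599 with that control and an estimated correlation.

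Several genes of secondary metabolism fell in GR14. Of 10 tested tryptophan and serotonin genes 3 fell and none rose, and 4 passed when adjusted over the list alone. T5H, which makes serotonin from tryptamine, fell by 1.01 ± 0.19, and the methyltransferases of melatonin synthesis ASMT1 and ASMT3 had log2 folds of -2.03 ± 0.46 and -3.28 ± 0.32, both past the test. T5H and ASMT1 did not pass with WT array 1 alone (-1.03 and -2.50). The tryptophan decarboxylase TDC2 had a log2 fold of -0.46 ± 0.22 (limma adjusted p 0.279). Of 18 tested shikimate and phenylpropanoid genes 5 fell and none rose, and 7 passed when adjusted over the list alone. They included the lignin enzymes CAD3, which fell by 1.67 ± 0.18, and 4CL3, which fell by 1.21 ± 0.21, and the shikimate entry enzyme DAHPS1, which fell by 1.14 ± 0.17. The 2 lists had camera adjusted p values of 0.018 and 0.00154, and an adjusted p of 0.266 each with an estimated correlation.

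Lists of the proteasome (adjusted p 0.00352), cytosolic ribosomal proteins (0.018) and the TCA cycle (0.0264) also passed in GR14, each with a negative median, although 0 of their 44 genes passed on the probe set that stands for the gene; another probe set of the TCA cycle gene SDH2-1 passed, with a log2 fold of -0.88 (adjusted p 0.0336). None of the 7 lists passed with an estimated correlation. By camera, other splits of the GR14 and WT arrays passed a median of 3 lists and at most 6, against 7 for the real groups. The number of lists is therefore weak evidence of an effect of the line. With WT array 1 alone the ribosomal list turned direction, with an adjusted p of 0.929, the TCA cycle list no longer passed (0.0836) and the jasmonate list passed (0.0474), with an adjusted p of 0.627 with that control and an estimated correlation. By fry, which tests whether the genes of a list move one way on balance, 7 lists passed in GR14: the ribosomal and TCA cycle lists did not (adjusted p 0.371 and 0.129), and the sugar transport and WRKY lists did (0.0105 each). By fry 0 lists passed in 35S-15 and 0 in HFL1. By camera the other 14 lists had adjusted p values of 0.065 and above. Of the 8 aspartate-family genes, which include those of lysine synthesis, SAMS2, an S-adenosylmethionine synthetase, fell by 1.04 ± 0.12, although another SAMS2 probe set had a log2 fold of -0.40 (adjusted p 0.321), and no other gene passed. The lysine synthesis genes DAPB1, DAPB2, DAPF and LYSA had log2 folds of -0.07, 0.11, 0.14 and 0.13 in GR14, 0.03, 0.43, 0.03 and -0.04 in 35S-15 and 0.05, 0.68, 0.08 and -0.04 in HFL1, none past the test. No glutelin, prolamin or seed albumin gene passed. Among starch synthesis genes SSI rose by 1.26 ± 0.31 (0.82 with WT array 1 alone, not past the test) and SSII-2 fell by 1.61 ± 0.23, although another SSII-2 probe set had a log2 fold of 0.84. The glutamate dehydrogenase gene GDH2 rose by 1.03 ± 0.19, although 2 other probe sets had log2 folds of 0.48 and 0.69 that did not pass, and the glutamine synthetase gene GLN1-1 fell by 1.04 ± 0.21.

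The naming rule also gave these genes in GR14. WRKY76 rose by 3.88 ± 0.75, the jasmonate signalling repressor JAZ2 by 3.33 ± 0.51, the stress kinase gene SAPK9 by 2.58 ± 0.25, the light-regulated gene LIR1 by 2.52 ± 0.28 and the heat shock factor HSF03 by 2.30 ± 0.40. BBD1 rose by 3.01 ± 0.19 and CDKE;1 by 2.88 ± 0.64, although another CDKE;1 probe set had a log2 fold of 0.20 (adjusted p 0.424). GLU12 fell by 5.67 ± 1.47, CLA1 by 4.67 ± 0.54, RAA1 by 3.55 ± 0.60 and the cytokinin oxidase gene CKX4 by 3.10 ± 0.37, and the sugar transporter SWEET2B had a log2 fold of -3.7 ± 0.43. Another CLA1 probe set had a log2 fold of -0.79 (adjusted p 0.0991). The GR14 means of OsBiP4, GLU12, CLA1, RAA1, SWEET2B and CKX4 (2.29, 1.44, 3.55, 2.62, 5.55 and 5.71) lay below the mean of the GR14 array medians, 5.92, so the size of these falls is uncertain. The limma adjusted p of these genes was 0.0397 or less. WRKY76, JAZ2, HSF03, CDKE;1, GLU12 and RAA1 no longer passed with WT array 1 alone as control, where they had log2 folds of 3.68, 2.39, 2.00, 3.47, -3.73 and -3.43.

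In 35S-15, 9 probe sets differed from WT, 8 higher and 1 lower, and in HFL1 9 were higher and 0 lower. The split depends on WT array 1, without which 12 were higher and 3 lower in 35S-15 and 11 higher and 7 lower in HFL1. The named gene of the rule was MT2B, a metallothionein, which rose by 2.56 ± 0.29 in 35S-15, although 3 other probe sets of the gene had log2 folds of -0.072, 0.0064 and -0.84, and with WT array 1 alone it did not pass (2.56). Beyond LOC4331398 and LOC9268308, 2 probe sets without a gene name rose in both lines, by 5.35 and 2.89 in 35S-15 and by 5.39 and 2.42 in HFL1. Both also rose in GR14, by 5.31 and 4.04, and passed there, so they are not particular to these 2 lines. The 1 lower probe set in 35S-15, also without a gene name, had a log2 fold of -4.14, of uncertain size, as its 35S-15 mean of 3.77 lies below the array median. An unadjusted p under 0.05 was seen for 1969 and 2142 probe sets, where 1590 are expected by chance. The counts with WT array 1 alone were 26 and 24. CCA1 had log2 folds of -0.38 in 35S-15 and -0.12 in HFL1, neither past the test.

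The photosynthesis list was higher in both lines, with a median log2 fold of 0.41 in 35S-15 and 0.39 in HFL1 (camera adjusted p 1.26e-09 and 2.6e-09), and adjusted p values of 0.291 and 0.229 with an estimated correlation. None of its 14 genes passed over all probe sets, and 9 and 6 passed when adjusted over the list alone. In 35S-15 the prolamin and seed albumin, glutelin, heat shock and pathogenesis-related lists were also higher (median log2 folds 0.71, 0.34, 0.45 and 0.28), and the TCA cycle and DNA replication lists were lower (-0.14 and -0.22). In HFL1 the pathogenesis-related list and the list of glutathione S-transferases and peroxidases were higher (0.27 and 0.23) and the endoplasmic reticulum chaperone list was lower (-0.19). None passed with an estimated correlation, where the adjusted p of each was 0.229 or more. When the arrays of each comparison were split between the 2 groups in other ways, a median of 5 lists passed by camera. The real groups gave 7 in 35S-15 and 4 in HFL1, so these lists cannot be read as effects of the lines. With WT array 1 alone the 4 additional higher lists of 35S-15 and its 2 lower lists, and the chaperone and pathogenesis-related lists of HFL1, no longer passed. With that control the aspartate-family list passed in 35S-15 and HFL1 (adjusted p 0.000919 and 0.00259), as did the ribosomal list (0.00423 and 0.0429), the jasmonate list in 35S-15 (0.011) and the embryo and aleurone list in HFL1 (0.021). With that control and an estimated correlation none of these passed (adjusted p 0.140 or more). TDC2 had log2 folds of -0.15 ± 0.22 and -0.50 ± 0.22 in 35S-15 and HFL1.

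**Figure D3:**
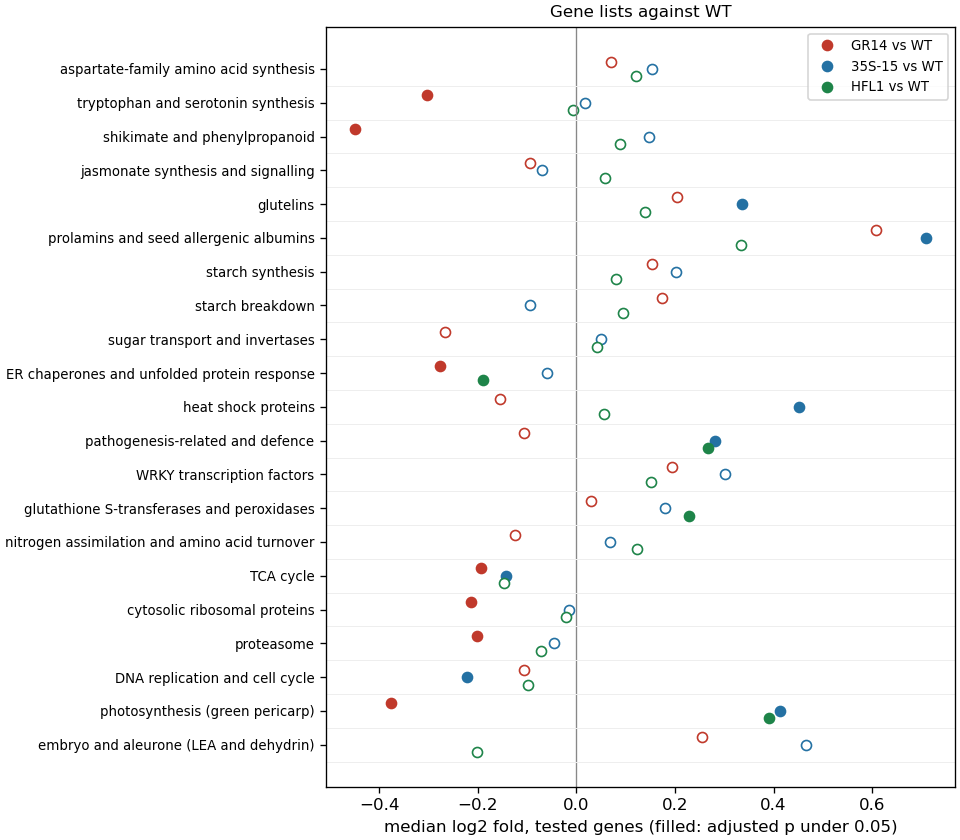
Median log2 fold (x axis) of the tested genes of each of 21 gene lists (y axis) in each line against WT; filled points have a camera adjusted p under 0.05 at the preset correlation. The photosynthesis list has a median of -0.38 in GR14 and of 0.41 and 0.39 in the other lines.

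The lines were then compared with one another. These contrasts leave out the WT means, but the WT arrays still entered the filter and the shared estimate of spread. HFL1 differed from GR14 on 2133 probe sets, 1246 higher and 887 lower, and 35S-15 differed from GR14 on 1889, 1088 higher and 801 lower. Fitted on the compared groups alone, the counts were 1862 for HFL1 and 1341 for 35S-15 against GR14. Single arrays also move these counts. Without HFL1 replicate 1 the first was 1166, 762 higher and 404 lower. Without GR14 replicate 2 the second was 1124, 750 higher and 374 lower. CCA1 was higher by 4.23 ± 0.20 in HFL1 and by 3.97 ± 0.20 in 35S-15 than in GR14, SWEET2B by 3.74 ± 0.43 and 3.77 ± 0.43, and RAA1 by 4.04 ± 0.60 and 4.05 ± 0.60. CLA1 was higher by 4.89 ± 0.54 in HFL1 (0.58 on another probe set, adjusted p 0.217) and ASMT3 by 4.09 ± 0.32 in 35S-15. PCL1 had log2 folds of -6.39 and -6.13 and JAZ2 of -3.22 and -3.43 in the 2 comparisons, and the metallothionein gene MT4C had one of -5.48 in HFL1; the HFL1 means of PCL1 and MT4C, 4.24 and 3.18, lay below the array medians, as did the GR14 means of CLA1, RAA1 and SWEET2B and the 35S-15 mean of LOC4340325, 5.43, so the sizes for these genes in this paragraph are uncertain. HFL1 and 35S-15 differed on 2 probe sets, LOC4340325, higher by 5.27 ± 0.43 in HFL1, and LOC4330940, with a log2 fold of -2.05 ± 0.25; an unadjusted p under 0.05 was seen for 1418, where 1590 are expected by chance.

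The mean of the 3 lines differed from WT on 35 probe sets, 25 higher and 10 lower, and on 66 with WT array 1 alone. Of the 35, 24 passed singly in GR14 alone, 4 in 2 lines and 4 in all 3, so most are not calls that the lines share; CCA1, with log2 folds of -4.35, -0.38 and -0.12 in GR14, 35S-15 and HFL1, is 1 of the 24. No gene with an informative symbol met the naming rule. Probe sets called in the same direction in at least 2 lines numbered 9, and 4 were called in all 3, including both of LOC4331398. Simulated unchanged groups with independent noise, against shared controls, gave 0.04 on average and at most 1 for at least 2 lines. They held no line with many calls and no unlike WT arrays. The overlap that shared controls can give in these data therefore stays unknown. Independent lists would share 0.245 probe sets between GR14 and 35S-15, 0.243 between GR14 and HFL1 and 0.00226 between 35S-15 and HFL1, against 5, 6 and 6 observed. With 3 controls they could not be split into 2 sets of at least 2 arrays, so part of the excess may come from the shared controls.

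HFL1 departed from the sum of the GR14 and 35S-15 differences on 498 probe sets, 324 higher and 174 lower, and on 290 with WT array 1 alone. CCA1 was above the sum by 4.61 ± 0.28, CLA1 by 4.48 ± 0.76 (0.35 on another probe set, adjusted p 0.702), CKX4 by 4.23 ± 0.52 and SWEET2B by 3.68 ± 0.61. MT4C, which did not pass in GR14 against WT, had a departure of -6.38 ± 1.25, JAZ2 of -3.13 ± 0.72, SAPK9 of -2.86 ± 0.36 and HSF03 of -2.78 ± 0.56. The departures of MT4C, JAZ2 and HSF03 did not pass with WT array 1 alone (-6.23, -2.19 and -2.47). The departures of CLA1, CKX4, SWEET2B and MT4C have uncertain sizes, since a group mean of each lies below the array medians. LOC4331398, high to the same level in all 3 lines, had one of -7.78 ± 0.56.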

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

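The tests of the reporter pattern and of effects shared with HFL1, and the counts of splits, were chosen after the results were seen; the tests on PRR1 and PCL1, on the pericarp and on RNA degradation were written before those values were looked at, when CCA1 and GI were known.

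The differences between lines were flagged because the lines' effects differ by a direct test: 2133 probe sets for HFL1 against GR14, 1889 for 35S-15 against GR14, 2 for HFL1 against 35S-15, and 498 for the departure from the sum. The pattern behind them is that GR14 stands apart. Sampling of GR14 at another time of day is a candidate explanation: it needs the evening genes PRR1 and PCL1 to rise while CCA1 falls, and the lower of their log2 folds was 0.85. A smaller share of green pericarp stays open. The prediction was that a lost tissue would lower the clock genes. Instead 3 of them, GI, PRR1 and PCL1, rose by more than 0.5 on the log2 scale and passed the test. This does not decide, since no value here shows that the clock genes are pericarp transcripts. Without GR14 array 3 only GI of these passed, while PRR1 and PCL1 had log2 folds of 0.88 and 4.64. With WT array 1 alone the log2 folds of GI, PRR1 and PCL1 were 1.41, 0.92 and 4.77. For an effect that GR14 shares with HFL1, the median HFL1 fold in the direction of GR14 over the 1799 GR14 calls was 0.078. The median GR14 fold size was 1.16, which the choice of these calls raises. Of the calls, 1225 were called the other way in HFL1 against GR14. The choice was made on GR14 and not on HFL1, and the shared WT arrays pull both folds the same way. The comparison behind the 1225 holds the GR14 arrays by which the 1799 were chosen, so that count decides nothing. The HFL1 median shows only that the typical HFL1 fold on these probe sets was small. Whether GR14 and HFL1 share an effect stays undecided, since the calls were chosen for standing out in GR14. RNA degradation stays open: all 3 GR14 arrays lay inside the range of the other 9 for 1 of 5 control transcripts, although for 0 of 5 were all 3 above the others. GR14 array 3 was the highest of 12 for 3 of 5 and the lowest for 1, and 1427 probe sets differed without it. A change of the clock in GR14 itself stays open and was not tested, since the labels give no time of collection.

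The reporter probe set RPTR-Os-K01193-1_at was flagged as a signal outside the tested probe sets, at 13.51 and 13.79 in WT arrays 2 and 3. A swap of these arrays with 2 arrays of GR14 is argued against, since every such swap is a split of GR14 and WT. The highest count of the other splits was 1 there, against 1799. For 35S-15 and HFL1 the highest counts of the other splits were 1 and 3 against 9 and 9. These are too few calls to decide. Swaps with arrays of different lines are not among these splits. LOC4331398 was lower in both WT arrays than in the lowest line array by at least 6.66 on the log2 scale. It was chosen because it follows the labels and does not decide. A wrong label or material of another genotype stays open, and no biological explanation was tested, since the design gives none. Of 66 pairs of arrays, WT arrays 2 and 3 were jointly highest by over 1 on the log2 scale for 10 probe sets, a count passed only by 38 for GR14 arrays 1 and 2, and jointly lowest for 10, a count passed by 48 pairs.

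In the 3-against-3 comparisons the 10 splits of 6 arrays cannot give a share under 0.05. Each real count is given with the highest count of the other splits. Against WT they were 1799 and 1 for GR14, 9 and 1 for 35S-15, and 9 and 3 for HFL1. Against GR14 they were 2133 and 0 for HFL1 and 1889 and 3 for 35S-15. For HFL1 against 35S-15 they were 2 and 53, where 2 of the 10 splits, the real one included, reached the real count. For gene lists they were 7 and 6 in GR14, 7 and 9 in 35S-15 and 4 and 11 in HFL1. There 1, 2 and 6 of the 10 splits, the real one included, gave as many lists. Over 100 regroupings of the 12 arrays, the real one included, 2 gave as many probe sets as the 35 of the mean of 3 lines (highest other 232). The 498 of the departure were reached by 1 (highest other 16) and the 9 shared calls by 1 (highest other 1). These 3 shares lie under 0.05, but the regroupings also scatter the 3 GR14 arrays, which stand apart. They therefore cannot tell a difference between WT and the lines from that of GR14 alone. Which arrays the regrouping with 232 joined was not examined.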

How the results depend on the processing

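No paired analysis was possible because the sample titles carry no replicate number within a group. WT array 1 alone, chosen after seeing the data, leaves 1 control, assumed to vary like the other groups. The causes were not tested, except that fewer probe sets or arrays entered where the setting says so. With WT array 1 alone, 747 probe sets differed in GR14, 26 in 35S-15, 24 in HFL1, 66 for the mean of lines and 290 for the departure from the sum; 4 lists passed in 35S-15, 29 calls were shared and 28 of the 55 called named values tested again kept their call. The ribosomal list turned direction in GR14, 35S-15 and HFL1 (adjusted p 0.929, 0.00423 and 0.0429). Without the intensity trend 1160 differed in GR14, 17 for the mean, 1259 for 35S-15 against GR14 and 253 for the departure. At 2-fold, 1084 differed in GR14, 1225 for HFL1 and 1134 for 35S-15 against GR14. With 1 probe set per gene, 3 differed in 35S-15, 2 in HFL1, 11 for the mean and 1 between HFL1 and 35S-15. The mean gave 23 without _x_at and _s_at probe sets and 79 with array weights. With an estimated correlation 0 lists passed in each line, and 0 with WT array 1 alone as well, where the ribosomal list turned direction in GR14 (adjusted p 0.970).

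Leaving out each array gave 972 to 1805 probe sets in GR14 (972 without GR14 replicate 2, 1007 without WT replicate 2, 1170 without WT replicate 1), 8 to 15 in 35S-15 and 6 to 18 in HFL1 (15 and 18 without WT replicate 1), 14 to 53 for the mean (without WT replicates 2 and 3), 1166 to 2156 for HFL1 against GR14 (without HFL1 replicate 1 lowest), 1124 to 1909 for 35S-15 against GR14 (without GR14 replicate 2 lowest), 1 to 3 for HFL1 against 35S-15, and 297 to 534 for the departure (without HFL1 replicate 1 lowest). Lists ran from 5 to 10 in GR14, 3 to 11 in 35S-15 and 4 to 9 in HFL1, shared calls from 7 to 19 and kept named values from 52 to 71. Other probe sets turned the sign of CAT-B (-0.46), PRX112 (0.34), SSII-2 (0.84) and SUT2 (0.68) in GR14 and of MT2B (-0.072 and -0.84) in 35S-15. Over all settings but other probe sets, 1374 of 1516 tests of called named values kept call and direction and 142 lost the call, and 20 of 5003 tests of uncalled values gained one. Some of these tests left out an array that is not in the comparison. On other probe sets of the same genes, only 7 of 26 tests of called named values kept call and direction. There 13 lost the call and 6 turned direction. Quantile normalization, median centring, the offset of 50 and both filters kept every total of calls within 1.5 times, but not every count of lower calls. Median centring gave 16 for the mean of lines (main 10). In 35S-15 there were 2 under both scalings and the offset and 0 at the 70th percentile (main 1). In HFL1 there was 1 under quantile normalization and 1 with no filter (main 0). Dim probe sets limit what could be seen, since no detection calls were used.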

Other observations

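The observations in this part were picked out after the values were seen. The tests of METK3, Pir7b and the chaperone list against all WT arrays belong to the planned comparisons. METK3, an S-adenosylmethionine synthetase of the aspartate family, had log2 folds of 0.49 ± 0.52 in GR14, 1.07 in 35S-15 and 1.29 in HFL1 against WT, none past the test. With WT array 1 alone as control they were 2.27, 2.85 and 3.07. The pathogenesis-related gene Pir7b had a log2 fold of 1.47 ± 0.34 in HFL1 (limma adjusted p 0.476). NFYB1 had log2 folds of -0.72, -0.91 and -0.81 in GR14, 35S-15 and HFL1, of which only the first passed (limma adjusted p 0.0151), and the mean of the 3 lines passed with -0.81 (0.0292).

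Besides OsBiP4, SAT1 was higher in WT arrays 2 and 3 (log2 signals 12.28 and 12.48) than in WT array 1 (10.88) and in every array of the lines. The lower endoplasmic reticulum chaperone list in HFL1 may come from the WT arrays that carry the reporter signal: its camera adjusted p of 0.000668 became 0.805 with WT array 1 alone. In GR14 the same list stayed past the threshold with WT array 1 alone (adjusted p 0.0474), but its adjusted p was 0.599 with that control and an estimated correlation, and 0.266 with all WT arrays and an estimated correlation.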
